A study of Mus musculus with 12 samples.

How the data were processed

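Striatum was taken at 8 weeks and frozen, and 100 ng of total RNA per sample was labelled for Affymetrix whole-transcript arrays, per the labels' protocols. The authors' deposited values are log2 expression values per probe set, made with RMA, per the submitters' processing notes. Its version, background and summary settings and any filter on probe sets are not given in the sources used here. RMA includes a normalization between arrays, so a shift shared by most genes would not be seen. Scanner files and detection calls were not used here, so no probe set could be called above background, and the log2 values run from 1.99 to 13.77. No genome build or coordinates are given by the submitters in the sources used here. Gene positions were taken from a separate gene table (GRCm38.p6).

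Groups and replicate numbers were taken from the titles of the samples, which call them biological replicates. Each was taken as 1 mouse. P-values measure the spread between these samples. The 12 arrays correlated at 0.988 to 0.995 within groups, and no pair within a group held identical values (SD of the difference between arrays 0.172 to 0.271). The same replicate numbers appear in each group, and nothing in the labels ties them to a litter or day. Xist lay between 5.59 and 5.86 in all 12 mice and the Y-linked gene Uty between 8.92 and 9.43, so that sex did not vary between groups.

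Of 24055 probe sets, 19942 had 1 gene symbol in the platform table, 1225 had several and 2888 were not listed. Entrez gene IDs of 19886 of the 19942 matched the gene table (GRCm38.p6), which updated 0 symbols. For 470 genes with more than 1 probe set, the one with the highest mean over all 12 mice was used, leaving 19248 genes. Of called genes for the mean HD effect with several probe sets (182), all probe sets passed for 142, and 0 genes had probe sets called in both directions. Probe sets with several symbols or none were tested but not named.

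limma 3.58.1 in R 4.3.3 was used to fit a mean per group to all 12 arrays (8 residual degrees of freedom, prior degrees of freedom 4.14), with eBayes without trend or robust fitting. Contrasts were the HD effect with p62, the HD effect without p62, the p62 effect in non-transgenic and in HD mice, the difference of the HD effects and the means of the HD and of the p62 effects. P-values were adjusted by Benjamini-Hochberg over all genes within a contrast, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 22 lists, with an estimated correlation and fry as alternatives. The sex-linked list served only as the check above, and the red blood cell list had under 3 members measured and was not tested. Of 542 list entries, 492 were measured. The HD score and its exact permutation of p62 genotype within HD status used 400 assignments.

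Tests, lists and the rule for naming genes were likewise fixed in advance. The rule took, per contrast, the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap, and the 5 smallest p where none passed. From each list it took up to 4 members past the threshold with the smallest p and the brightest member that did not pass. It also took Sqstm1 and any gene within 10 Mb of it past the threshold in a p62 contrast. Symbols of predicted genes (Gm or LOC with digits, or ending in Rik) were counted and not named. Among the genes called for the HD effect with p62, 1364 of 1366 did not overlap between groups. Of all genes 33.07% did not, where chance gives 10%.

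The fits, camera and the HD score were tested on simulated data with the real gene means and residual SDs and independent noise (19248 genes, 200 changed). For the HD effect with p62, 54 of 100 genes changed by 0.5 and 95 of 100 changed by 1 on the log2 scale were recovered, with 13 false calls. For the HD effect without p62 the numbers were 56, 94 and 1. For the mean HD effect they were 80, 98 and 15. A list shifted by 0.3 was the 1 list called of 22, with the preset and with the estimated correlation. An HD effect made 1.5 times larger without p62 gave an HD score difference of 0.206 (exact permutation p = 0.015), and equal effects gave -0.00115 (p = 0.72). Real arrays share variation that the simulation leaves out.

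Alternatives chosen before the data were examined were the replicate number as a block, quantile normalization of the log2 values again, equal array medians, leaving out genes below the 25th or 50th percentile of mean brightness, all probe sets or their average per gene, trended and robust variances, array weights, only the 2 groups compared, Xist as a covariate, thresholds of 0.01 and 0.1, other gene choices for the HD score and leaving out each mouse in turn. Alternatives chosen after seeing the data were leaving out 3 arrays of small spread, each array's SD or its choroid plexus mean as a covariate, the list tests after quantile normalization, and exact permutation of list means per mouse. The 3 arrays (HD_p62KO replicate 1, HD_p62WT replicate 2 and NT_p62KO replicate 3) have an SD over all genes of 1.66, 1.64 and 1.58, furthest below their group's median (1.71, 1.70 and 1.66). The SD ran from 1.64 to 1.73 in HD mice and from 1.58 to 1.67 in non-transgenic mice. Array spread as a covariate can therefore also take up part of the HD effect.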

Results

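The data were gene expression values from the striatum, the forebrain nucleus that degenerates most in Huntington's disease (HD), of 12 mice aged 8 weeks. The mice fell into 4 groups of 3. They were non-transgenic or carried an HD transgene, and had normal p62 or a p62 knockout. p62, encoded by Sqstm1, is a receptor that binds ubiquitinated cargo for autophagy. The cross asked how loss of p62 changes the transcriptome of the HD model. Whole-transcript arrays gave 1 value per probe set and mouse, and 19248 genes were tested. The array medians lay between 7.70 and 7.73 on the log2 scale. With 3 mice per group, the number of arrays limits the precision of each value.

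Sqstm1 was low in each of the 6 mice labelled as knockouts. In non-transgenic mice its log2 value was 11.26 ± 0.079 (SD, n = 3) with normal p62 and 8.49 ± 0.038 (SD, n = 3) in the knockouts, a log2 difference of -2.78 ± 0.11 (SE; limma, adjusted p = 1.05e-07). In HD mice the values were 11.51 ± 0.25 and 9.03 ± 0.10, a difference of -2.48 ± 0.11 (SE; adjusted p = 4.03e-07). Between HD and non-transgenic knockouts, the remaining Sqstm1 signal rose by 0.54 ± 0.11 (SE; adjusted p = 0.0076). With normal p62 the HD difference was 0.24 ± 0.11 (SE; adjusted p = 0.18), and the 2 HD differences were not told apart (0.30 ± 0.15, adjusted p = 0.991).

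**Figure D1:**
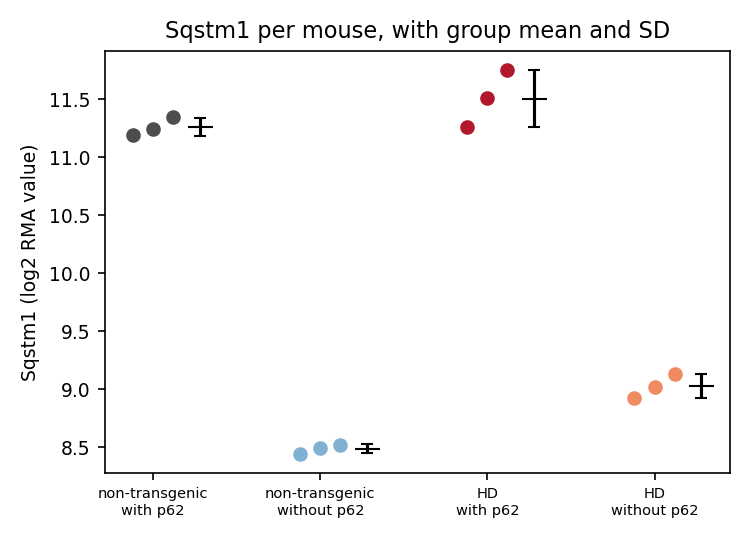
Sqstm1 log2 value per mouse (points) in the 4 groups, with the group mean and SD (bars, n = 3 each). The 6 knockout mice lie between 8.44 and 9.13 and the 6 mice with normal p62 between 11.19 and 11.75.

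In mice with normal p62, the HD transgene was accompanied by lower expression of genes of striatal projection neurons. Scn4b, a sodium channel subunit enriched in these neurons, fell by 1.77 on the log2 scale (SE 0.085, n = 3 per group, 3.40-fold; limma, adjusted p = 1.37e-06). Cnr1, the CB1 cannabinoid receptor, fell by 1.18 (SE 0.093, adjusted p = 0.000131). Rasgrp2 fell by 0.89 (SE 0.078, adjusted p = 0.000207) and the phosphodiesterase Pde10a fell by 0.76 (SE 0.075, adjusted p = 0.000336). Of 39 measured medium spiny neuron genes, 27 fell, 3 rose and 9 did not pass the test, and 29 fell and 3 rose when adjusted over the list alone. The list's median log2 fold change was -0.44 (camera, adjusted p = 2.49e-18; adjusted p = 0.185 with an estimated correlation). Gng7, the brightest member that did not pass, differed by -0.07 ± 0.08 (SE).

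Markers of striatal interneurons were also lower in these HD mice. Chat, the acetylcholine-synthesizing enzyme of cholinergic interneurons, fell by 1.12 (SE 0.21, adjusted p = 0.0101), and Slc5a7, the choline transporter, fell by 0.58 (SE 0.11). Nos1 fell by 0.54 (SE 0.072) and Sst, encoding somatostatin, fell by 0.47 (SE 0.081). In all, 6 of 14 measured interneuron markers fell and 0 rose, with 7 lower when adjusted over the list alone (camera, adjusted p = 1.92e-06). It was the only list of the 22 tested that also passed with an estimated correlation (adjusted p = 0.0147). Cck, the brightest marker that did not pass, differed by -0.57 ± 0.29 (SE).

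Activity-regulated immediate early genes, induced by neuronal firing, were lower as a group in HD mice with normal p62. Npas4 fell by 1.09 (SE 0.27), Egr3 fell by 0.64 (SE 0.068), Egr1 fell by 0.61 (SE 0.13) and Ier5 fell by 0.47 (SE 0.080). Of 22 measured members 5 fell over all genes and 12 when adjusted over the list alone, and all 22 had a negative fold change (camera, adjusted p = 3.56e-08; adjusted p = 0.185 with an estimated correlation). Genes of cholesterol synthesis showed the same direction. Msmo1, a sterol oxidase, fell by 0.81 (SE 0.14), Insig1 fell by 0.54 (SE 0.096), Srebf2, the transcription factor that drives the pathway, fell by 0.42 (SE 0.067) and Nsdhl fell by 0.33 (SE 0.067). Of 19 measured members 7 fell, and 11 when adjusted over the list alone (camera, adjusted p = 7.14e-08; adjusted p = 0.217 with an estimated correlation).

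Interferon-stimulated genes were higher in HD mice with normal p62. Irf9, part of the transcription factor complex that answers type I interferon, rose by 0.82 ± 0.10 (SE; adjusted p = 0.00125), Gbp3 by 0.73 ± 0.13, the MHC class I light chain B2m by 0.60 ± 0.11 and Usp18 by 0.53 ± 0.086. Of 21 measured members 9 rose and 0 fell, and 10 rose when adjusted over the list alone (camera, adjusted p = 3.52e-07; adjusted p = 0.129 with an estimated correlation). Psat1, Shmt2 and Asns, enzymes of serine, glycine and asparagine metabolism that are targets of ATF4, rose by 0.49 ± 0.085, 0.48 ± 0.11 and 0.29 ± 0.069. They were the 3 members that passed among 30 genes of the unfolded protein and integrated stress response (4 when adjusted over the list alone; camera, adjusted p = 0.0491; adjusted p = 0.724 with an estimated correlation). The chaperone Calr in that list differed by 0.05 ± 0.09 (SE). The stress response list no longer passed without HD_p62WT replicate 1 or 3, NT_p62KO replicate 2 or 3 or any 1 NT_p62WT mouse (camera, adjusted p = 0.0505 to 0.228).

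Of the 22 lists, 14 passed for this comparison, 5 upward and 9 downward. Those with no member past the threshold, over all genes or over the list alone, included the respiratory chain (median 0.08; camera, adjusted p = 0.0158), autophagy (0.11; adjusted p = 0.0296), homeobox (-0.09; adjusted p = 0.0165) and thalamic, septal and pallidal neuron lists (-0.24; adjusted p = 0.0154). With an estimated correlation these had adjusted p = 0.781, 0.762, 0.756 and 0.724. The respiratory chain list no longer passed without HD_p62WT replicate 1 or 3 (adjusted p = 0.228 and 0.0595), the autophagy list without either of these or NT_p62WT replicate 1 (0.16, 0.0992 and 0.0743), and the thalamic, septal and pallidal list without HD_p62WT or NT_p62WT replicate 2 (0.0967 and 0.29). After quantile normalization the homeobox and autophagy lists had adjusted p = 0.0511 and 0.085. With array spread as a covariate the respiratory chain, autophagy and homeobox lists had adjusted p = 0.749, 0.651 and 0.504. The respiratory chain and homeobox lists each had 0.0645 with the choroid plexus mean as a covariate. Without the 3 arrays of small spread the thalamic, septal and pallidal list had 0.106 (all with camera). Among 23 NRF2 target genes Blvrb fell by 0.49 (SE 0.067) and among 24 NF-kappaB and inflammatory genes the chemokine Cxcl1 fell by 0.42 (SE 0.11). Each was the only one in its list, also when adjusted over the list alone, and neither list passed (camera, adjusted p = 0.478 and 0.519). The heat shock, choroid plexus and ependymal lists did not pass either (adjusted p = 0.323, 0.108 and 0.519).

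Some glial markers were lower in these mice. Among 17 mature oligodendrocyte markers, Fa2h fell by 0.43 (SE 0.083), Mal fell by 0.39 (SE 0.077), Cldn11 fell by 0.37 (SE 0.093) and Car2 fell by 0.44 (SE 0.12), and 5 fell when adjusted over the list alone (camera, adjusted p = 0.0336; adjusted p = 0.781 with an estimated correlation). Mbp, encoding myelin basic protein, differed by -0.0015 ± 0.067 (SE). The oligodendrocyte list no longer passed without HD_p62WT replicate 2 (adjusted p = 0.399), whose list mean was -0.21 against 0.04 and 0.03 in the other mice of its group, or without NT_p62WT replicate 2 (0.242). Nor did it pass after quantile normalization (adjusted p = 0.057) or without the 3 arrays of small spread (0.447). Among 18 astrocyte markers the glutamate transporter Slc1a2 fell by 0.32 (SE 0.061), the only one over all genes or over the list alone (camera, adjusted p = 0.00214, and 0.0503 without NT_p62WT replicate 2; adjusted p = 0.461 with an estimated correlation). Among 14 oligodendrocyte precursor markers Enpp6 rose by 0.57 ± 0.13 and Cacng4 fell by 0.51 (SE 0.069), 2 and 1 when adjusted over the list alone (camera, adjusted p = 0.576). No microglia marker of 18 and no endothelial or mural cell marker of 17 passed in limma, over all genes or when adjusted over the list alone (camera, adjusted p = 0.605 and 0.519). Markers of excitatory neurons of the neighbouring cortex had a median of -0.39 with 0 of 15 past the test (camera, adjusted p = 0.00214; adjusted p = 0.461 with an estimated correlation).

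Over all 19248 genes, 742 rose and 624 fell in HD mice with normal p62 (limma, Benjamini-Hochberg adjusted p below 0.05), and 4882 had an unadjusted p below 0.05, where chance gives 962.4. Of the 1366, 21 changed at least 2-fold. Outside the lists, the glutathione peroxidase Gpx6 fell by 1.76 (SE 0.16), Krt6b fell by 1.53 (SE 0.32), Abi3bp fell by 1.41 (SE 0.14), Cpne9 fell by 1.39 (SE 0.18), Phex fell by 1.22 (SE 0.091) and the orphan receptor Gpr139 fell by 1.16 (SE 0.093). The neuronal adhesion molecule Cntn6 rose by 1.84 ± 0.41 (SE), Trappc13 by 1.49 ± 0.25, the kinesin Kif4 by 1.28 ± 0.27, Nsun7 by 1.13 ± 0.13, Zfand4 by 1.13 ± 0.22 and Tmc3 by 1.01 ± 0.10. Tex30, the importin Kpna4, Fsd1l and Taf4b rose by 0.93 to 0.98. The count depended on single mice, from 398 genes without HD_p62WT replicate 3 to 2040 without NT_p62KO replicate 3, and was 421, 441, 845 and 440 without HD_p62WT replicate 1 and NT_p62WT replicates 1, 2 and 3. Without the 3 arrays of small spread it was 3320. The share of higher genes among those called was 54.3%, but 47.8% with equal array medians, 44.4% with array spread or with the choroid plexus mean as a covariate, 49.4% with a replicate block and 39.1% at an adjusted p below 0.01, and 40.1%, 36.4%, 45.6% and 39.5% without HD_p62WT replicates 1 and 3 and NT_p62WT replicates 1 and 3.

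In mice without p62, the HD transgene was accompanied by the same direction of change in projection neuron genes. Scn4b fell by 1.88 (SE 0.085, n = 3 per group, 3.69-fold; limma, adjusted p = 6.50e-07), Cnr1 fell by 1.28 (SE 0.093), Pde10a fell by 0.94 (SE 0.075) and the muscarinic receptor Chrm4 fell by 0.87 (SE 0.075). Of 39 medium spiny neuron genes 31 fell and 2 rose, with 32 lower and 3 higher when adjusted over the list alone (camera, adjusted p = 1.78e-17; adjusted p = 0.267 with an estimated correlation). Tac1, encoding substance P, did not pass (0.23 ± 0.091 SE, adjusted p = 0.0853). Among 14 interneuron markers 4 fell, and 5 when adjusted over the list alone (camera, adjusted p = 0.00431; adjusted p = 0.20 with an estimated correlation). They were Slc5a7 (-0.48), Nos1 (-0.39), Chodl (-0.37) and Sst (-0.30).

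Interferon-stimulated genes and proteasome subunits were higher in HD mice without p62. Ifit3 rose by 1.24 ± 0.17 (SE; adjusted p = 0.00122), Irf9 by 1.10 ± 0.10, B2m by 0.77 ± 0.11 and Usp18 by 0.60 ± 0.086. Of 21 interferon-stimulated genes 10 rose, the same number when adjusted over the list alone (camera, adjusted p = 6.22e-06; adjusted p = 0.20 with an estimated correlation). Of 31 proteasome subunits 11 rose, and 19 when adjusted over the list alone, among them Psmd1 by 0.88 ± 0.19, Psmc6 by 0.43 ± 0.099, Psmd6 by 0.39 ± 0.084 and Psma3 by 0.35 ± 0.081 (camera, adjusted p = 5.48e-06; adjusted p = 0.52 with an estimated correlation). In mice with normal p62, Psmd1 was the 1 subunit that rose and 0 passed over the list alone (camera, adjusted p = 0.000706, and 0.0651 with array spread as a covariate; adjusted p = 0.724 with an estimated correlation). The difference between the HD effects on proteasome subunits passed with camera (adjusted p = 0.00475) but not with an estimated correlation (adjusted p = 0.709), by exact permutation (adjusted p = 0.5995), or with camera without HD_p62WT replicate 2 (0.224) or NT_p62KO replicate 3 (0.186).

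Among glial markers in HD mice without p62, the microglia markers Cd53 and Ctss, a lysosomal protease, rose by 0.40 ± 0.081 (SE; adjusted p = 0.0086) and 0.35 ± 0.092 (adjusted p = 0.0208), 2 of 18 over all genes and over the list alone. Of 17 mature oligodendrocyte markers 6 fell, among them Fa2h (-0.46 ± 0.083) and Ugt8a (-0.37 ± 0.099), and of 18 astrocyte markers 4 fell, among them Slc1a2 (-0.27 ± 0.061) and Ntsr2 (-0.37 ± 0.11), the same numbers when adjusted over the list alone. None of these 3 lists passed (camera, adjusted p = 0.228, 0.0534 and 0.0779). Of 15 cortical excitatory neuron markers, with a median of -0.36, Rspo1 fell by 0.40 (SE 0.094), 1 over all genes and over the list alone, and that list did not pass either (camera, adjusted p = 0.0534). The differences between the HD effects with and without p62 did not pass for these 4 lists (adjusted p = 0.182, 0.793, 0.265 and 0.414).

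Immediate early genes and cholesterol genes were lower in HD mice without p62. Egr3 fell by 0.74 (SE 0.068), Egr1 fell by 0.50 (SE 0.13), Ier5 fell by 0.50 (SE 0.080) and Egr4 fell by 0.35 (SE 0.080). Of 22 members 7 fell, over all genes and over the list alone (camera, adjusted p = 3.87e-05; adjusted p = 0.483 with an estimated correlation). Msmo1 fell by 0.76 (SE 0.14), Insig1 fell by 0.52 (SE 0.096), Cyp51 fell by 0.48 (SE 0.12) and Srebf2 fell by 0.37 (SE 0.067), and 5 of 19 cholesterol genes fell, 9 when adjusted over the list alone (camera, adjusted p = 0.00034; adjusted p = 0.52 with an estimated correlation). In the stress response list 9 of 30 rose, 10 when adjusted over the list alone, again with Shmt2 (0.61), Psat1 (0.50) and Asns (0.31), beside Edem1 (0.32), which acts in degradation of misfolded endoplasmic reticulum proteins (camera, adjusted p = 0.00369, and 0.0797 with array spread as a covariate; adjusted p = 0.52 with an estimated correlation). Of 22 heat shock and chaperone genes 6 rose, among them Chordc1 (0.48) and Dnajb1 (0.43), the same number when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0534). In all, 11 of the 22 lists passed for this comparison, 6 upward and 5 downward, and with an estimated correlation 0 did.

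Some genes of the autophagy and NRF2 lists, both tied to p62 function, rose in HD mice without p62. Of 28 autophagy genes, Tax1bp1, a cargo receptor, rose by 0.40 ± 0.13 (SE), Atg3 by 0.38 ± 0.12, Atg7 by 0.24 ± 0.067 and Ulk1 by 0.19 ± 0.058, with 0 when adjusted over the list alone (camera, adjusted p = 0.00272; adjusted p = 0.625 with an estimated correlation). Of 23 NRF2 target genes 7 rose and 1 fell, 9 and 1 when adjusted over the list alone, led by Mgst1 (0.62 ± 0.11), Txnrd1 (0.38 ± 0.089) and Ftl1 (0.36 ± 0.074) and with Blvrb lower (-0.39 ± 0.067) (camera, adjusted p = 0.0444; adjusted p = 0.625 with an estimated correlation). The NRF2 list no longer passed without NT_p62KO replicate 3 (adjusted p = 0.102), HD_p62KO replicate 2 (0.152) or after quantile normalization (0.108). NT_p62KO replicate 3 had the lowest mean of the 12 mice in both lists (-0.19 for autophagy and -0.18 for NRF2 target genes). The difference between the HD effects did not pass for autophagy (adjusted p = 0.0818), and for NRF2 target genes it passed with camera (adjusted p = 0.0142) but not with an estimated correlation (adjusted p = 0.709) or by exact permutation (adjusted p = 0.5995). Of 37 respiratory chain subunits 4 rose, over all genes and over the list alone, including Ndufv1 by 0.35 ± 0.072 (camera, adjusted p = 0.000466; adjusted p = 0.625 with an estimated correlation). Of 37 homeobox and developmental transcription factors 6 fell, including Hoxc6 (-0.40) and Gata3 (-0.56), and 1 when adjusted over the list alone (camera, adjusted p = 0.000568; adjusted p = 0.612 with an estimated correlation). Both named genes were dim, with mean log2 values of 6.02 and 6.59, and across all genes the fold change correlated with mean brightness (r = 0.244, and 0.00516 after quantile normalization, over genes that are not independent replicates). After quantile normalization the homeobox list had adjusted p = 0.00495. With each array's spread as a covariate the autophagy, NRF2, respiratory chain and homeobox lists no longer passed (adjusted p = 0.531, 0.816, 0.666 and 0.225). Array spread itself tended to be higher in HD mice, so this covariate can also take up part of the HD effect.

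Over all genes, 2566 rose and 1606 fell in HD mice without p62 (limma, adjusted p below 0.05), and 7465 had an unadjusted p below 0.05. Of these 4172, 46 changed at least 2-fold. Gpx6 fell by 2.07 (SE 0.16), Gpr139 fell by 1.52 (SE 0.093), Cpne9 fell by 1.51 (SE 0.18), Phex fell by 1.46 (SE 0.091), Clspn fell by 1.38 (SE 0.12), Abi3bp fell by 1.37 (SE 0.14), Coch fell by 1.29 (SE 0.18) and Clec10a fell by 1.20 (SE 0.27). Nexmif rose by 1.72 ± 0.30 (SE), Cntn6 by 1.60 ± 0.41, Rab9 by 1.51 ± 0.45, the MHC gene H2-Q2 by 1.41 ± 0.31, Nfu1 by 1.35 ± 0.29, Ss18 by 1.32 ± 0.25, Alg13 by 1.23 ± 0.31, Wbp11 by 1.21 ± 0.39 and the splicing factor Srsf3 by 1.14 ± 0.20. The count was 1273 without HD_p62KO replicate 2, 1795 without HD_p62KO replicate 3 and 1876 without NT_p62KO replicate 3. With each array's spread as a covariate it was 843, of which 36.9% were higher, against 61.5% of the 4172.

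The HD effects in the 2 p62 genotypes, which share no mouse, went the same way across genes (Pearson r = 0.765, Spearman rho = 0.757 over 19248 genes, which are not independent replicates). Of the genes that rose with normal p62, 646 also rose without p62, where independent lists would share 98.92. Of those that fell, 461 also fell, against 52.06, and 0 genes were called in opposite directions. For the mean of both HD effects, 3838 genes rose and 2890 fell (limma), and 9020 had an unadjusted p below 0.05. Across genes the fold change correlated with mean brightness (r = 0.219, and 0.00529 after quantile normalization), so dim genes tended to fall. These counts therefore need not all be an HD response. After quantile normalization 6174 genes passed. With each array's spread as a covariate 2541 passed, and with equal array medians 49.9% of the genes called were higher, against 57.05%. Scn4b fell by 1.82 (SE 0.060), Gpx6 fell by 1.91 (SE 0.11) and Car12, a carbonic anhydrase, fell by 1.07 (SE 0.18), while Cntn6 rose by 1.72 ± 0.29 and Nipal2 by 1.03 ± 0.21.

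With both genotypes pooled, 32 of 39 medium spiny neuron genes fell and 3 rose, 12 of 22 immediate early genes fell, 11 of 19 cholesterol genes fell, 10 of 21 interferon-stimulated genes rose and 18 of 31 proteasome subunits rose. Adjusted over the list alone the counts were 32 and 3, 17, 13, 11 and 22. The camera adjusted p were 7.81e-16, 9.82e-07, 5.61e-06, 1.41e-06 and 7.80e-06. With an estimated correlation they gave adjusted p = 0.272, 0.272, 0.37, 0.154 and 0.536. Of 28 autophagy genes 13 rose and 1 fell, also 13 and 1 when adjusted over the list alone, with Lamp2 at 0.31 and Gabarap at 0.23 (camera, adjusted p = 0.00435, and 0.497 with array spread as a covariate; adjusted p = 0.594 with an estimated correlation). Of 15 cortical excitatory neuron markers 4 fell, over all genes and over the list alone, namely Nptx1 (-0.83 ± 0.24 SE), Nrn1 (-0.75 ± 0.21), Slc30a3 (-0.44 ± 0.11) and Rspo1 (-0.30 ± 0.067) (median -0.30; camera, adjusted p = 0.00851; adjusted p = 0.536 with an estimated correlation). The mean of that list per mouse had an exact permutation adjusted p = 0.055. It varied within groups, from 0.01 to 0.50 in NT_p62WT and -0.19 to 0.45 in NT_p62KO mice. In HD_p62WT and HD_p62KO mice it ran from -0.34 to -0.14 and from -0.36 to 0.07. Cortex taken along in the dissection could move these markers too, which was not tested. Taking each list's mean per mouse, 7 lists reached the smallest exact permutation p that 400 assignments allow (p = 0.005, adjusted p = 0.0157, two-sided), namely the medium spiny neuron, interneuron, immediate early, cholesterol, interferon, proteasome and astrocyte lists, and 10 of 22 had an adjusted p below 0.05.

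**Figure D2:**
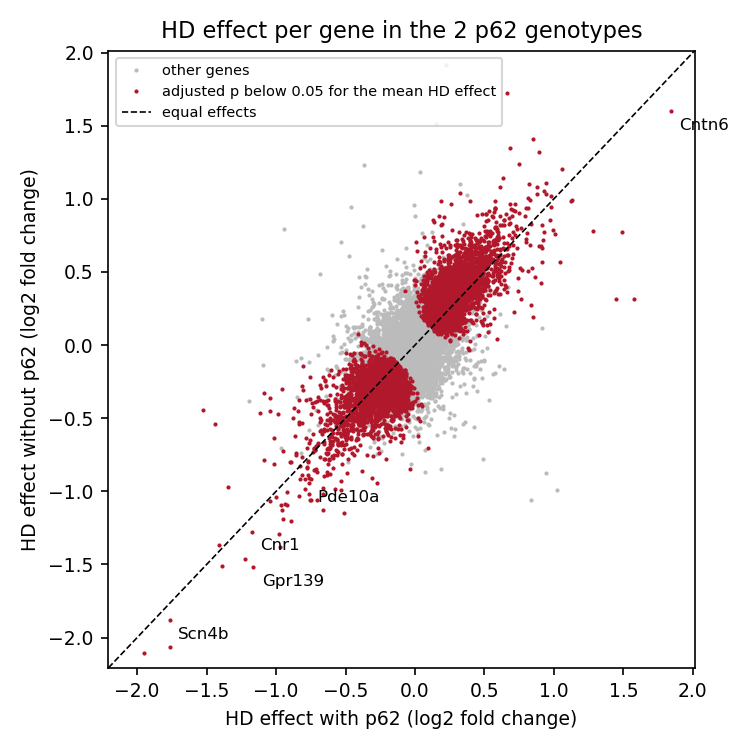
HD effect (log2 fold change) with p62 on the horizontal axis and without p62 on the vertical axis for 19248 genes (points; red, adjusted p below 0.05 for the mean HD effect), with a dashed line of equal effects. The points follow the line (r = 0.765), and Scn4b lies at -1.77 and -1.88.

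Loss of p62 in non-transgenic mice was accompanied by a change in 1 gene past the threshold, Sqstm1. In HD mice Sqstm1 was again the 1 gene. With both backgrounds combined 2 genes passed, Sqstm1 (-2.63 ± 0.076 SE, adjusted p = 3.19e-09) and Lyrm7 (-1.08 ± 0.11 SE, adjusted p = 0.00382), a mitochondrial assembly factor gene. Lyrm7 lies within 10 Mb of Sqstm1 in the GRCm38.p6 gene table. It differed by -1.04 in non-transgenic and -1.12 in HD mice, and without the 3 arrays of small spread it no longer passed (-1.06, adjusted p = 0.354). The numbers of genes in the 3 comparisons with an unadjusted p below 0.05 in limma were 639, 555 and 518, each under the 962.4 that chance gives. In simulated data with 200 changed genes, 92 of 100 genes changed by 0.5 were recovered for the combined p62 comparison, and 61 of 100 and 48 of 100 for those in non-transgenic and in HD mice. The adjustment is stricter where few genes change, so these rates do not carry over to these comparisons. Anxa6, at -0.488 ± 0.086 (SE) for the combined comparison, had adjusted p = 0.6435 (limma). The p62 effects in the 2 backgrounds had r = -0.017 across genes (rho = -0.11). Leaving out 1 mouse at a time moved r from -0.087 (HD_p62WT replicate 3) to 0.112 (NT_p62KO replicate 3).

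Choroid plexus markers, genes of the tissue that makes cerebrospinal fluid, had the largest median difference by p62 genotype of the 22 lists. All 14 measured markers were higher without p62 in non-transgenic mice (median 0.62; camera, adjusted p = 2.31e-13; adjusted p = 0.843 with an estimated correlation) and in HD mice (median 0.28; camera, adjusted p = 0.00261; adjusted p = 0.76 with an estimated correlation). In HD mice the list no longer passed without HD_p62KO replicate 2 (adjusted p = 0.249, in the opposite direction) or HD_p62WT replicate 3 (0.498). For both together the median was 0.47 (camera, adjusted p = 3.26e-15; adjusted p = 0.388 with an estimated correlation), and the list mean per mouse had an exact permutation p = 0.105 (two-sided). No marker passed the test, over all genes or when adjusted over the list alone. Ttr, encoding transthyretin, differed by 2.27 ± 0.90 (SE) in non-transgenic and 0.26 ± 0.90 in HD mice. The list mean was -0.50 ± 0.15 (SD, n = 3) in non-transgenic mice with p62 and 0.41 ± 0.12 in those without, and -0.11 ± 0.60 and 0.19 ± 0.94 in the HD groups.

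**Figure D3:**
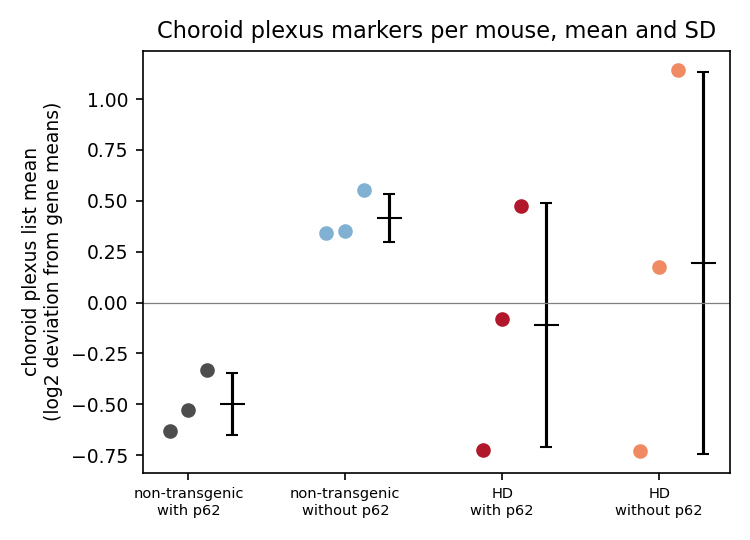
Mean log2 deviation of 14 choroid plexus markers from their gene means, per mouse (points), with the group mean and SD (bars, n = 3 each). HD mice without p62 range from -0.73 to 1.14, wider than the 0.34 to 0.55 of non-transgenic mice without p62.

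Other lists had small medians in the knockouts, and 0 of their members passed over all genes or over the list alone. NRF2 target genes had a median of -0.11 in non-transgenic mice (camera, adjusted p = 0.000277; adjusted p = 0.843 with an estimated correlation) and 0.01 in HD mice (adjusted p = 0.99). Interferon-stimulated genes had a median of 0.13 in HD mice (camera, adjusted p = 0.0011; adjusted p = 0.523 with an estimated correlation), with B2m at 0.24 ± 0.11 (SE). Without HD_p62KO replicate 2, whose list mean of 0.42 was above the 0.14 and 0.21 of its group, this list did not pass (adjusted p = 0.21), and without NT_p62KO replicate 3 the NRF2 list in non-transgenic mice did not (0.103). HD_p62KO replicate 2 also had the highest choroid plexus mean, 1.14. Medium spiny neuron genes had a median of 0.03 in non-transgenic mice (camera, adjusted p = 0.0379; adjusted p = 0.843 with an estimated correlation) and, in the opposite direction, -0.06 in HD mice (camera, adjusted p = 0.000171; adjusted p = 0.751 with an estimated correlation). Their call in non-transgenic mice ended with the choroid plexus mean as a covariate or a replicate block (camera, adjusted p = 0.106 and 0.051). Thalamic, septal and pallidal markers (0.11) and heat shock genes (0.05) also passed in HD mice (camera, adjusted p = 0.00537 and 0.00812; adjusted p = 0.751 and 0.751 with an estimated correlation). Ependymal markers had medians of 0.11 and 0.13 (camera, adjusted p = 0.00464 and 0.00582; adjusted p = 0.843 and 0.751 with an estimated correlation). With the choroid plexus mean as a covariate neither ependymal call passed (camera, adjusted p = 0.986, in the opposite direction, in non-transgenic mice and 0.055 in HD mice). Microglia markers had a median of -0.07 in non-transgenic mice (camera, adjusted p = 0.0121; adjusted p = 0.843 with an estimated correlation). Autophagy genes had medians of -0.05 and 0.00 and did not pass (adjusted p = 0.0953 and 0.457). Single mice ended further calls in non-transgenic mice, for medium spiny neuron genes without NT_p62KO or NT_p62WT replicate 2 (adjusted p = 0.363 and 0.547), microglia markers without the same 2 mice (0.052 and 0.547) and ependymal markers without NT_p62KO or NT_p62WT replicate 3 (0.186 and 0.0947). In HD mice they ended those for the thalamic, septal and pallidal list without HD_p62KO replicate 1 or HD_p62WT replicate 2 (0.0609 and 0.0951), heat shock genes without HD_p62KO or HD_p62WT replicate 2 (0.104 and 0.708) and ependymal markers without HD_p62KO replicate 2 or 3 (0.109 and 0.247). In all, 9 lists passed in non-transgenic mice, 9 in HD mice and 6 for both together, and with an estimated correlation 0 did. The first count was 4 and 5 without NT_p62KO and NT_p62WT replicate 3, and the last was 3 without HD_p62KO replicate 1 and 10 without HD_p62WT replicate 2.

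**Figure D4:**
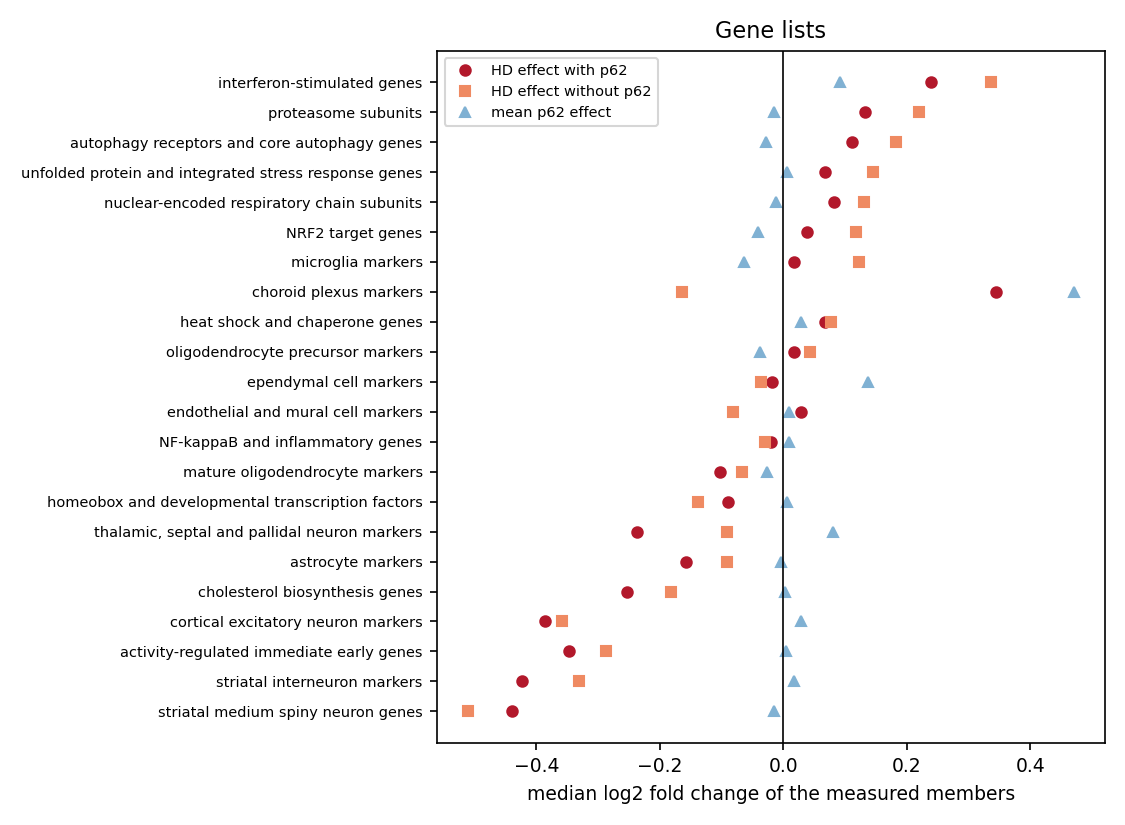
Median log2 fold change of the measured members of 22 gene lists (rows) for the HD effect with p62 (circles), the HD effect without p62 (squares) and the mean p62 effect (triangles). Medium spiny neuron genes lie at -0.44 and -0.51 for the HD effects and at -0.02 for the p62 effect.

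The difference between the HD effects with and without p62 asked directly whether p62 alters the response to the HD transgene. In limma 0 genes passed, and 665 had an unadjusted p below 0.05, where chance gives 962.4. The 5 genes with the smallest p were Glb1l3 (-0.76 ± 0.14 SE), Akna (-0.63 ± 0.13), Cwc27 (0.70 ± 0.16), Tulp2 (-0.76 ± 0.18) and Mok (0.55 ± 0.13), each with adjusted p = 0.991. In simulated data for this comparison, 84 of 100 genes changed by 1 and 30 of 100 changed by 0.5 were recovered. The simulation held 200 changed genes, and the adjustment is stricter where fewer change, so these rates do not carry over here. Medium spiny neuron genes had a median difference of -0.10, a larger decrease without p62 (camera, adjusted p = 5.44e-05, and 0.0981 without NT_p62KO replicate 2; adjusted p = 0.709 with an estimated correlation). The proteasome list had a median difference of 0.10 (camera, adjusted p = 0.00475, and 0.224 and 0.186 without HD_p62WT replicate 2 and NT_p62KO replicate 3; adjusted p = 0.709 with an estimated correlation). By exact permutation of list means 0 of the 22 lists passed (the smallest adjusted p = 0.5995).

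The HD score, the mean signed deviation over the 6728 genes that passed for the mean HD effect, summed up the size of the HD effect in each mouse. Its genes were chosen and signed by the HD effect in these same mice, so its separation of HD from non-transgenic mice was built in. The score was higher in HD mice by 0.275 with p62 and by 0.342 without, a ratio of 1.24. The difference of 0.067 was within what reassigning p62 genotype gave (exact permutation p = 0.29, two-sided, smallest possible 0.005). The HD score difference was 0.0286, 0.0331 and 0.0438 without HD_p62WT replicate 2, NT_p62KO replicate 3 and NT_p62WT replicate 2, and 0.11 and 0.122 without NT_p62KO replicate 2 and HD_p62KO replicate 1 (exact permutation p = 0.12 to 0.635). The group means were -0.14 ± 0.028 (SD, n = 3) and -0.17 ± 0.072 in non-transgenic mice with and without p62, and 0.14 ± 0.052 and 0.17 ± 0.061 in HD mice. The medium spiny neuron list in place of these genes gave a difference of 0.083 (exact permutation p = 0.195).

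**Figure D5:**
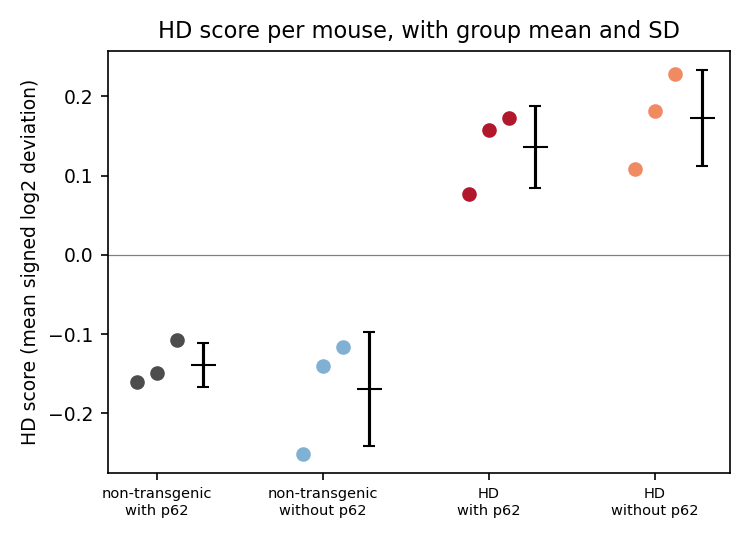
HD score (mean signed log2 deviation over 6728 genes) per mouse (points) in the 4 groups, with the group mean and SD (bars, n = 3 each). HD mice lie between 0.077 and 0.229 and non-transgenic mice between -0.251 and -0.108, a separation built in by choosing the genes in these same mice.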

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

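All tests that weigh explanations in this part (the arrays of small spread, the HD score as an explanation, the genes near Sqstm1 and the choroid plexus markers) were chosen only after the result was seen. The counts over other splits of the samples were set before the splits were run, except those for genes near Sqstm1 and for the mean p62 effect with Sqstm1 left out.

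The difference between the HD effects with and without p62 was tested for each gene list, and 9 of 22 lists passed with camera's preset correlation. The difference (without minus with p62) was negative for medium spiny neuron genes (median -0.10, adjusted p = 5.44e-05), choroid plexus markers (-0.41, adjusted p = 0.00695), endothelial and mural markers (-0.11, adjusted p = 0.0142) and homeobox genes (-0.08, adjusted p = 0.024). For medium spiny neuron and homeobox genes this was a larger fall in HD mice (medians -0.44 and -0.09 with p62, -0.51 and -0.14 without). It was positive for proteasome subunits (0.10, adjusted p = 0.00475), NRF2 target genes (0.09, adjusted p = 0.0142), respiratory chain subunits (0.07, adjusted p = 0.0294), interneuron markers (0.13, adjusted p = 0.0355) and stress response genes (0.06, adjusted p = 0.0413). For interneuron markers this was a smaller fall (median -0.42 with p62 and -0.33 without). With an estimated correlation the adjusted p was 0.65 for the interneuron markers and 0.709 for each of the others. The number of lists was 2 without NT_p62KO replicate 3, 14 without NT_p62WT replicate 1, 5 without each of HD_p62KO replicate 1, HD_p62KO replicate 2 and NT_p62WT replicate 2, and 4 after quantile normalization. Each of the 9 calls ended without at least 1 mouse, with a largest adjusted p of 0.0981 for medium spiny neuron genes (without NT_p62KO replicate 2), 0.648 for choroid plexus markers (HD_p62KO replicate 1), 0.165 for endothelial markers (HD_p62WT replicate 3), 0.645 for homeobox genes (NT_p62KO replicate 3), 0.204 for NRF2 target genes (HD_p62KO replicate 2) and 0.0966 for interneuron markers (HD_p62KO replicate 3). Without HD_p62WT replicate 2 it was 0.224 for proteasome subunits, 0.902 for respiratory chain subunits and 0.738 for stress response genes. Of 100 splits of the mice, 39 gave as many lists (real 9, highest other 15), so chance was not excluded.

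Probe sets that no gene comparison used were also tested. For the mean HD effect, 748 of 2888 probe sets absent from the platform table and 415 of 1225 with several gene symbols passed. Of the 19248 genes 6728 did, so neither share was above that of the genes.

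Of 100 splits of the mice by HD status within p62 genotype, 1, the real one, gave as many genes for the mean HD effect (real 6728, highest other 3172), so chance was excluded. For the mean p62 effect 1 of 100 gave as many (real 2, highest other 1). One of the 2 genes is the deleted gene itself. With Sqstm1 left out 6 of 100 gave as many (real 1, highest other 1), so chance was not excluded for a count of 1 gene. That count takes any gene that passes, so it cannot decide whether Lyrm7 itself differs by chance. For the difference all 100 splits did (real 0, highest other 1), which a real count of 0 fixes in advance, so nothing follows from it. For the lists of the mean HD effect 15 of 100 did (real 13, highest other 16) and of the mean p62 effect 69 of 100 (real 6, highest other 14), so chance was not excluded for the number of lists.

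For comparisons of 3 mice with 3, the 10 splits are too few for a share under 0.05. For the HD effect with p62, 1 of 10 gave as many genes (real 1366, highest other 0) and 1 of 10 as many lists (real 14, highest other 13). For the HD effect without p62 it was 1 of 10 (real 4172, highest other 0) and 5 of 10 (real 11, highest other 14). For the p62 effect in non-transgenic mice it was 2 of 10 (real 1, highest other 1) and 4 of 10 (real 9, highest other 9), and in HD mice 1 of 10 (real 1, highest other 0) and 4 of 10 (real 9, highest other 13).

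More genes passed for the HD effect without p62 than for the HD effect with p62, 3.05 times as many, but the counts were 2416 against 1799 with Xist as a covariate, 6663 against 4625 with array weights, 1742 against 1406 with only the 2 groups compared, 3498 against 1731 without the dimmest 50% and 4480 against 669 with the choroid plexus mean as a covariate. The order turned with array spread as a covariate (843 without p62 against 1328 with it) and without NT_p62KO replicate 3 (1876 against 2040), and the counts were 1273 against 1223 and 1795 against 1027 without HD_p62KO replicates 2 and 3, and 3786 against 421, 3609 against 398, 3663 against 441, 3869 against 845 and 3730 against 440 without HD_p62WT replicates 1 and 3 and NT_p62WT replicates 1, 2 and 3. Array spread itself tended to be higher in HD mice, so its covariate can also take up part of the HD effect. Sex did not vary between groups, so Xist as a covariate does not adjust for sex. One candidate explanation is the 3 arrays of small spread, without which the ratio was 1.11. However, 7 of the 27 ways of leaving out 1 array from each of the same 3 groups gave a ratio as low. A larger HD effect without p62 is another, and the HD score difference had an exact permutation p = 0.29. The explanations cannot be told apart with 3 mice per group.

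Lyrm7 lies near Sqstm1. Of 226 genes within 10 Mb, with Sqstm1 left out, 18 had an unadjusted p below 0.05 for the mean p62 effect (7.97%, against 2.69% of all genes). Lyrm7, which prompted the test, is among the 18. Only 0.333% of windows elsewhere had as high a share, as DNA of the strain in which the knockout was made could give, while an effect of p62 loss that does not depend on position would put 7.97% within the usual range of windows. The 18327 windows were each centred on a gene and overlap, so 0.333% is not a p-value and can stem from few regions. However, 18 of 100 splits of the mice gave as high a share near Sqstm1 (real 7.97%, highest other 17.7%), so chance was not excluded. The ratio to the share of all genes, computed after that, was 2.96, and 1 of 100 splits was as high (highest other 2.38). The explanations cannot be told apart, since the strain background of the knockout is not given in the sources used here.

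Choroid plexus markers were higher without p62. Their deviations from group means moved together from mouse to mouse (median pairwise correlation 0.883, against at most 0.31 in 1000 random lists of matched brightness), as pieces of choroid plexus in some dissected samples could give, and Ttr ran from 8.36 to 12.21 among HD mice without p62. An effect of p62 loss on these genes stays open, with an exact permutation p = 0.105 for the list mean (difference 0.61).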

How the results depend on the processing

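Leaving out the 3 arrays of small spread, the array spread and choroid covariates, the list tests after quantile normalization and the exact permutation of list means were tests chosen only after the result was seen. Of 6063 results for named genes under alternatives, 5492 kept direction and side of the threshold, 571 no longer passed and 0 reversed. Only genes that passed in these same mice were counted, some in several comparisons, so the lack of reversals was nearly built in. The cause was not tested for the values below, except where fewer samples or another threshold sets it.

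Replicate numbers did not pair the samples. Deviations of same-numbered samples correlated at -0.337 to 0.206 (4 of 18 pairs over 0.1), and 2 of 12 samples correlated best with their own number. With a replicate block the HD effect with p62 gave 709 genes.

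Array weights gave 4625 and 6663 genes for the HD effects with and without p62. Xist as a covariate, which does not adjust for sex here since sex did not vary, gave 2416 without p62. Fitting only the 2 groups compared gave 1742. An adjusted p below 0.01 gave 276 and 969, and 3224 for the mean HD effect. An adjusted p below 0.1 gave 2799 and 6465. Without the 3 arrays of small spread the HD effect with p62 gave 3320, of which 1275 were among the 1366. With array spread as a covariate, which can also take up part of the HD effect, the HD effect without p62 gave 843 and the mean HD effect 2541. With the choroid plexus mean as a covariate the HD effect with p62 gave 669.

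The p62 effect in HD mice gave 2 genes without the dimmest 25%, 2 with trend and robust variances, 2 with array weights and 3 at an adjusted p below 0.1. In non-transgenic mice only the 2 groups compared gave 4. The mean p62 effect gave 1 without the dimmest 50% and 1 without the 3 arrays of small spread. Lyrm7 was dim, at 6.68 to 7.12 in knockouts and 7.63 to 8.26 with normal p62, against array medians of 7.70 to 7.73. The brightness filter may therefore have removed it before testing, so the first count does not show that it failed.

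Lists past the threshold with an estimated correlation were 1 for the HD effect with p62 and 0 for each other comparison. With fry they were 6 and 7 for the HD effects with and without p62, and 0 for both p62 effects, their mean and the difference. After quantile normalization 4 lists passed for the difference. By exact permutation they were 0 for the difference and 0 for the mean p62 effect. Without the 3 arrays of small spread 4 lists passed for the p62 effect in non-transgenic mice and 5 for the difference. With array spread as a covariate 9 passed for the HD effect with p62 and 3 for the difference, and with the choroid plexus mean 5 and 5 for the p62 effects in non-transgenic and HD mice.

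Leaving out 1 array at a time gave 398 to 2040 genes for the HD effect with p62 and 1273 to 5128 without. It gave 1 to 1 and 1 to 2 for the p62 effects in non-transgenic and HD mice, 0 to 1 for the difference, 4977 to 7542 for the mean HD effect and 2 to 2 for the mean p62 effect. Lists ranged from 10 to 15 and 11 to 15 for the HD effects, 4 to 11 and 6 to 9 for the p62 effects, 2 to 14 for the difference, 12 to 15 for the mean HD effect and 3 to 10 for the mean p62 effect. The mean p62 effect on Sqstm1 ran from -2.69 to -2.57 and the HD score difference from 0.0286 to 0.122. No detection values were used here, so signal over background was not assessed.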

Other observations

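The gene families here, the counts for them and the single genes in the last paragraph were tests chosen only after the result was seen, 24 families by the start of the gene symbol.

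Genes of the clustered beta protocadherins, cell-surface molecules that give neurons distinct identities, were higher in HD mice. For the mean HD effect 18 of 22 rose and 0 fell (median 0.36, also 0.36 after quantile normalization; camera, adjusted p = 9.32e-08; adjusted p = 0.232 with an estimated correlation), with Pcdhb9 at 0.78 ± 0.099 (SE, n = 6 per group) and Pcdhb21 at 0.57 ± 0.071. Members of this cluster are similar in sequence, so their probe sets can share signal. Of 334 zinc finger genes named Zfp, 141 rose and 16 fell (median 0.15; camera, adjusted p = 2.74e-08; adjusted p = 0.155 with an estimated correlation), with Zfp442 at 0.84 ± 0.16. Of 35 DEAD-box helicases 17 rose and 2 fell, including Ddx58, a sensor of viral RNA, at 0.58 ± 0.088 (camera, adjusted p = 4.14e-05; adjusted p = 0.227 with an estimated correlation). Of 10 SR splicing factors 8 rose (camera, adjusted p = 0.000697; adjusted p = 0.227 with an estimated correlation).

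Potassium channel genes were lower in HD mice. Of 85, 35 fell and 4 rose (median -0.16, and -0.17 after quantile normalization), with Kcnh4 at -0.84 ± 0.044 (SE), Kcnh3 at -0.72 ± 0.065 and Kcnip2 at -0.61 ± 0.075. This family also passed with an estimated correlation (camera, adjusted p = 1.26e-07; adjusted p = 0.0174 with an estimated correlation). Of 19 calcium channel genes 9 fell, including Cacnb1 at -0.42 ± 0.050 (camera, adjusted p = 0.00252; adjusted p = 0.12 with an estimated correlation). For these 6 families the median kept its sign after quantile normalization and with equal array medians. So did every other family tested except the contactins and contactin-associated proteins. The family mean per mouse had an exact permutation p = 0.005, the smallest possible (adjusted p = 0.0109). Others reached it too, among them mitochondrial ribosomal proteins, keratins and dual specificity phosphatases (camera, adjusted p = 4.55e-05, 4.80e-05 and 0.212). Neither check sets these 6 apart. Of 939 olfactory receptor genes 205 fell and 0 rose, with a median of -0.14 that was -0.04 after quantile normalization. These 205 are among the 2890 genes counted as lower for the mean HD effect.

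Chosen after its values were seen, the predicted gene Gm12695 was higher in HD mice by 1.00 ± 0.077 (SE, limma, adjusted p = 1.01e-05) (0.98 with p62 and 1.02 without), and the lowest HD mouse, at 6.67, lay above every non-transgenic mouse. Mouse Htt differed by 0.04 ± 0.055 (adjusted p = 0.606).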
